A study of Homo sapiens with 4 samples.

How the data were processed

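The series holds 4 microarrays with 2 colours each, one for each of 4 human prostate cancer cell lines grown with 1 µM 5-aza-2′-deoxycytidine (5-aza-dC), a nucleoside analogue that traps and depletes DNA methyltransferases. LNCaP and MDA-2A were treated for 5 days, PC3 for 4 days and DU145 for 3 days, per the labels. On each array the untreated control of the same line carried Cy3 and the treated sample carried Cy5, per the labels, and no array had the dyes swapped. A dye effect that a spot shows on every array therefore cannot be separated from the treatment in an average over the 4 lines.

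The deposited table gives 1 ratio of both channels per spot and array on a logarithmic scale, for 43008 spots, and the deposited values were taken as log2. Intensities, background values and spot flags were not used here. The authors' processing is not given in the sources used here beyond a design text that names a regression correlation. Blank cells, which make up 18611 spots for LNCaP, 17134 for DU145, 23193 for PC3 and 23823 for MDA-2A, show that spots were left out before the table was deposited, by a rule that the sources do not state. The base of the logarithm and the numerator of the ratio are not stated either. The values centre near 0 and reach 9.24, more than a base of 10 would allow on a 16-bit scanner. Base 2 was taken as the usual base for such arrays, and a natural logarithm is not excluded. All fold counts rest on base 2, and with a natural logarithm the same limits on the values would mean larger folds. The treated sample (Cy5) over the control (Cy3) was taken as the likely direction. This rests on the dyes in the labels and on the usual order of channels. With the other order every sign would turn. The deposited medians were −0.13 for LNCaP, −0.10 for DU145, −0.18 for PC3 and −0.16 for MDA-2A. Each array was centred on its median over all listed spots, so every ratio is relative to the median spot of its array.

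Spots were named through the platform annotation of 2016. It lists 17165 of the spots, 16485 with 1 gene symbol and 680 with several, and the other 25843 spots are unnamed here. Spots with several symbols named no gene. Gene IDs were looked up in a RefSeq gene table (assembly GRCh38.p14), used only for symbols, gene classes and neighbouring genes. Of the spots with 1 symbol, 16461 had a gene ID found there, and 0 symbols changed. Y-linked genes and XIST were left out (17 spots). Spots of the same gene were averaged per array. This gave 10582 named genes, of which 4617 had a value on all 4 arrays, 1328 on 3, 1260 on 2, 1275 on 1 and 2102 on none. A gene without a value is not measured here, which says nothing about its level.

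The cell line was the replicate (n = 4). Nothing repeats a line, so p-values measure the spread between these 4 arrays. Gene-level log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept, eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) for the 5945 genes measured on at least 3 arrays. The 5-day lines were compared with the 3- or 4-day lines in the same way for the 4617 genes on all 4 arrays. Duration and line are the same split in that comparison, and a dye effect shared by all arrays cancels in it. Within a line there is 1 array and no test, so genes at least 2-fold higher or lower are counted, beside the SD between spots of the same gene (0.51 in LNCaP, 0.53 in DU145, 0.53 in PC3 and 0.46 in MDA-2A). With 4 lines the smallest p of a two-sided exact sign-flip test is 0.125, so no single gene or list was tested that way.

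There were 20 gene lists, fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Lists with at least 5 tested members were tested with limma's cameraPR (correlation preset at 0.01, adjusted over the lists), 16 across the lines and 14 between the times. Camera with an estimated correlation and fry, both on genes with a value on all 4 arrays, were alternatives. With an estimated correlation, camera judges a list on the residual degrees of freedom of 4 arrays, where the preset form uses the number of genes. A list can hardly pass it here, so a call lost with it does not by itself show that the members are correlated. Across the lines it estimated a correlation of 0.76 for cell cycle genes, 0.20 for cancer-testis genes and 0.14 for cholesterol and fatty acid genes. The estimate was 0.04 for p53 targets, 0.009 for androgen-induced genes and −0.07 for heat shock genes. Where the members are more correlated than the preset 0.01, the preset form gives p-values that are too small. In each line, the median of a list was set against 10000 random lists of as many genes. The lists were fixed from general knowledge and not from these arrays.

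The named genes were those with the 10 highest and 10 lowest mean ratios across the lines, among those past the threshold, filled up with genes on all 4 arrays of the same sign in all 4 lines where fewer passed. Others were the 5 highest and 5 lowest in each line, the 5 most above and 5 most below 0 in the comparison of times (filled up with genes whose values in the 2 pairs of lines do not overlap), the 2 highest and 2 lowest members of each list, and 10 genes named in advance, of which 1 is not reported here. A gene named outside this rule was chosen after its values were seen.

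Alternatives included ratios as deposited, arrays scaled to the same spread, the median of a gene's spots, spots tested singly, genes on all 4 arrays, genes on at least 2 arrays, genes with several spots, robust eBayes, array weights, a 3-fold threshold and leaving out each line. Several were added after seeing the data. They were centring within 48 blocks of 900 consecutive spot numbers, centring within classes of spots listed on 1, 2, 3 or 4 arrays, a list test without the genes past the threshold, a list test on ranks, and 2-fold counts over genes on all 4 arrays. The blocks come from the numbering, in which all 188 missing numbers are the last 4 of a block.

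The fits were tested on simulated data. In each of 20 simulations 200 genes were changed, in equal parts by log2 1, 2, 4 and 8. Across the 4 lines, among 5945 genes, the test found 53.5% at 1, 95.1% at 2 and 99.7% at 4. Between the times, among 4617 genes and with 1 common SD for the changed genes, it found 1.1% at 1, 55.6% at 2 and 100% at 4. So many changed genes loosen the adjusted threshold. In the real data 2 genes passed across the lines and 1 between the times, so the threshold was stricter and these shares are too high for it. GPRC5A, at a mean of 2.17 across the lines, did not pass. The list test called a list moved by 0.5 in 100% of 100 simulations. The simulated genes were independent of each other. In the data the estimated correlation within lists lay between −0.07 for heat shock genes and 0.78 for mesenchymal and matrix genes, so this result does not carry over to correlated lists. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The number of arrays, 4, limits the precision of every value.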

Results

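Gene expression was measured in 4 human prostate cancer cell lines after treatment with the DNA demethylating drug 5-aza-dC, each against its own untreated culture on the same array. LNCaP is an androgen-sensitive line from a lymph node metastasis, MDA-2A an androgen-sensitive line from a bone metastasis, and DU145 and PC3 are androgen-insensitive lines from brain and bone metastases. All received 1 µM drug, LNCaP and MDA-2A for 5 days, PC3 for 4 days and DU145 for 3 days. There was 1 array per line. Of 43008 spots, 24397 had a ratio for LNCaP, 25874 for DU145, 19815 for PC3 and 19185 for MDA-2A. Through the annotation, 6899 named genes had a value in LNCaP, 7332 in DU145, 6162 in PC3 and 5854 in MDA-2A. Ratios are log2 values relative to the array median, and a positive ratio likely means a higher level in the treated cells, from the dyes in the labels and the usual order of channels. With the other order every sign below would turn, and the germ-cell genes described first cannot settle this.

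The first comparison asked which genes responded to the drug in all lines. The highest ratios belonged to genes that are normally active in male germ cells. PAGE2, of a family of germ-cell antigens, had a mean log2 ratio of 7.89 ± 0.06 (SD, n = 4), with 7.91 in LNCaP, 7.82 in DU145, 7.86 in PC3 and 7.96 in MDA-2A. MAEL, a factor of the piRNA pathway that silences transposons in the germ line, had a mean of 5.35 ± 1.43 (SD, n = 4) and values of 6.62, 6.56, 4.09 and 4.15 in the same order. Both were higher in 4 of 4 lines and were the 2 genes of 5945 that rose past the threshold, with limma adjusted p = 6.4e-07 for PAGE2 and 0.0272 for MAEL. No gene fell past it. At an unadjusted p under 0.05 there were 1326 genes, 861 higher and 465 lower, where chance alone gives 297. Each of PAGE2 and MAEL was read from 1 spot. Without LNCaP, DU145 or PC3 the mean of MAEL was 4.93, 4.95 and 5.78 and its adjusted p 0.164, 0.192 and 0.0792, in a range of 0.00683 to 0.192 over 8 alternatives. MAEL also did not pass with arrays scaled to the same spread, with robust eBayes or with genes on at least 2 arrays, where PAGE2 alone passed. These fits are not among the 8.

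Below the threshold, other genes had ratios of the same sign in all 4 lines. GCNA, a germ-cell nuclear protein, had a mean of 3.21 ± 2.39 (SD, n = 4; adjusted p = 0.107), with 6.02 in DU145 and 4.37 in LNCaP but 1.24 in PC3 and 1.22 in MDA-2A. INAVA, which takes part in innate immune signalling, had a mean of 2.30 ± 1.07, and GPRC5A, a receptor first found as a retinoic acid target, 2.17 ± 0.78 over 2 spots, from 1.07 in DU145 to 2.80 in LNCaP. The drug efflux transporter ABCG2 had a mean of 1.94 ± 2.07 that was set by 4.85 in MDA-2A. DNALI1, an axonemal dynein chain, had a mean of 1.86, the vesicle fusion protein VAMP8 1.76, phospholamban (PLN) 1.65 and beta-arrestin 1 (ARRB1) 1.62. Adjusted p for these 7 genes lay between 0.0698 and 0.167. At the other end, GNAL, a G protein alpha subunit, had a mean of −2.94 ± 2.05 (SD, n = 4), followed by the antisense RNA LHX4-AS1 at −1.84, SYT12 at −1.69, the importin IPO5 at −1.56, FAM163B at −1.51, the long non-coding RNA APRG1 at −1.502, NLGN1-AS1 at −1.48, the Notch ligand DLL4 at −1.43, the histone deacetylase HDAC4 at −1.42 and SEZ6L2 at −1.39. None of these 10 passed.

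The number of calls depended on which genes were tested together. When the fit held the 4617 genes with a value on all 4 arrays, 42 passed, 30 higher and 12 lower. They included INAVA, GPRC5A, PLN and ARRB1 with adjusted p between 0.0276 and 0.0454, and IPO5, FAM163B, NLGN1-AS1, DLL4 and HDAC4 with adjusted p between 0.0231 and 0.0459. Also among them were NSDHL, an enzyme of cholesterol synthesis, at 1.24 ± 0.07 (SD, n = 4), and BAG3, a partner of heat shock proteins, at 1.01 ± 0.31. The split of directions depended on centring: of the genes at an unadjusted p under 0.05, 64.9% were higher after centring and 34.2% with ratios as deposited.

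**Figure D1:**
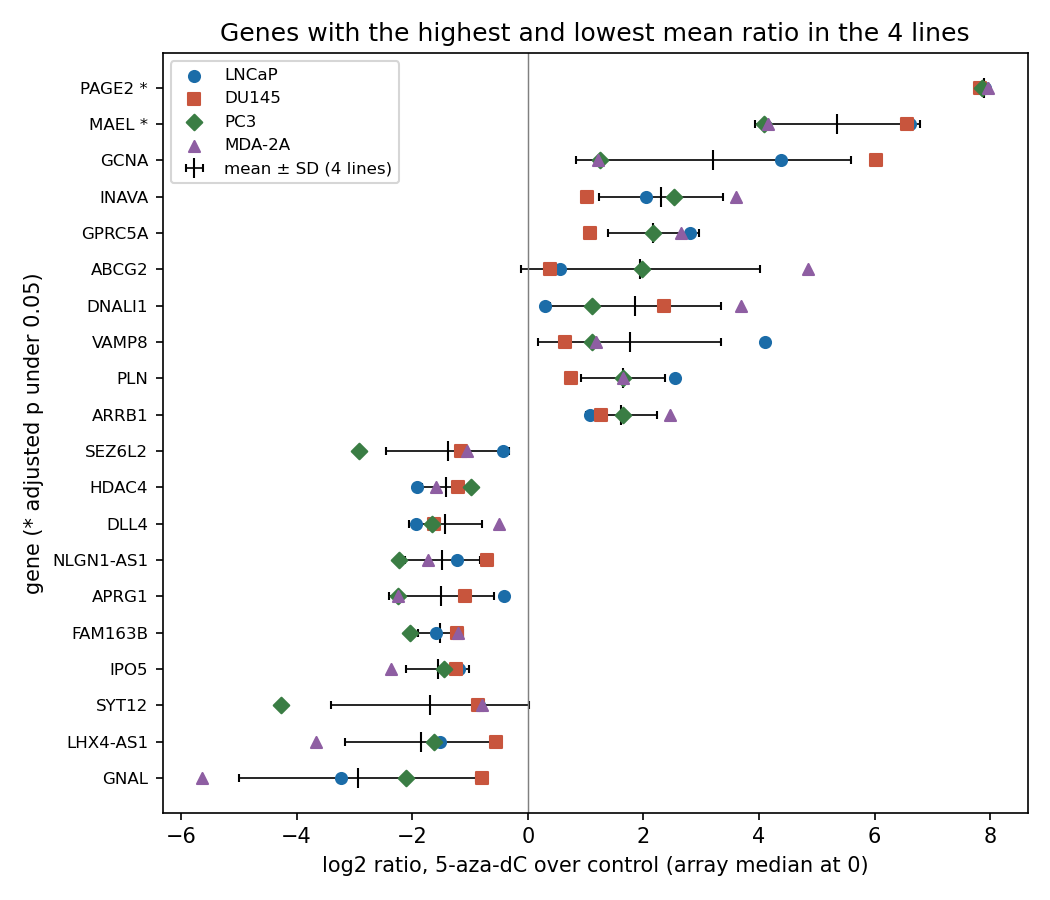
Log2 ratio of treated over control (x axis, array median at 0) for 10 genes with high and 10 with low mean ratios. Beyond the 2 that passed, these had the largest means among genes with a value on all 4 arrays and the same sign in each line. Tested genes outside this rule are not drawn, such as CALCOCO1 at a mean of −3.63 and TGM4 at 3.11, each on 3 arrays. Symbols mark the 4 cell lines, ticks and bars the mean and SD, and asterisks the 2 genes that passed the test; the 4 points of PAGE2 lie between 7.82 and 7.96.

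Gene lists were compared across the lines to see which groups of genes moved together. Cancer-testis genes, genes of germ cells that are methylated in most other tissues, rose as a list: 15 of 18 tested members had a mean above 0, and the list had an adjusted p of 6.6e-19 by cameraPR (adjusted p = 0.485 with an estimated correlation, which ended the call). Over all genes 2 of its members passed, and 4 did adjusted over the list alone, PAGE2, MAEL, SSX3 and MAGEC1. SSX3 had a mean of 2.37 ± 1.77 (SD, n = 4) and MAGEC1 1.502 ± 1.14 (SD, n = 3), whereas SSX2IP at −0.28 and MAGEA8 at −0.10 were the lowest tested members. Without PAGE2 and MAEL the list had an adjusted p of 0.0386. Its range over the alternatives was 1.5e-24 to 0.485. SSX3 and MAGEC1 were named after their values were seen.

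Genes of cholesterol and fatty acid synthesis also rose as a list, with 19 of 21 tested members above 0 (cameraPR adjusted p = 2.4e-04; adjusted p = 0.485 with an estimated correlation). EBP, a sterol isomerase, had a mean of 1.67 ± 0.73 (SD, n = 3) and NSDHL 1.24. IDI1 at 1.10, HMGCS1 at 0.79, STARD4 at 0.71 and SREBF2, a transcription factor of this pathway, at 0.57 passed with these 2 when adjusted over the list alone, 6 genes against 0 over all genes. These last 4 were named after their values were seen. With fry the list had an adjusted p of 0.0604, and the range over its alternatives was 4.7e-06 to 0.485. PMVK at −0.34 and HSD17B7 at −0.05 were the 2 tested members below 0. Heat shock and unfolded protein response genes rose as well (12 of 15 above 0, adjusted p = 0.0022; adjusted p = 0.479 with an estimated correlation; range 0.00102 to 0.479). Its highest members were EDEM1, which takes part in the disposal of misfolded proteins, at 1.01 and BAG3 at 1.01, and its lowest ERN1 at −0.12 and SESN2 at −0.06. Adjusted over the list alone 7 members passed, and over all genes 0.

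The other 13 lists did not pass. The list of core histones had 8 of 9 members above 0 (cameraPR adjusted p = 0.0747), with H4C8 at 1.44 and H2AZ2 at −0.22. It also holds the linker histone H1-2, at 0.63. The list test on ranks called core histones (adjusted p = 0.0301) and interferon-stimulated genes (adjusted p = 0.0472), both higher. The list test without the genes past the threshold also called core histones (adjusted p = 0.0467). Adjusted p was 0.149 for interferon-stimulated genes (15 of 16 above 0), p53 targets (17 of 21), androgen-induced genes (18 of 26) and leukocyte markers (4 of 5), and 0.180 for keratins and epithelial adhesion genes (16 of 18). Genes reported as silenced in prostate cancer had 12 of 15 members above 0 (adjusted p = 0.473), from DKK1, a Wnt inhibitor, at 1.39 and ID4 at 0.89 to LAMB3 at −1.28. Imprinted genes (6 of 8), mesenchymal and matrix genes (9 of 12) and ribosomal proteins (6 of 10) had an adjusted p of 0.621. Neuroendocrine and neuronal genes (4 of 5) and the DNA methylation machinery (7 of 14) had 0.805, and cell cycle genes (20 of 28) 0.827. Leaving out 1 line, cell cycle genes passed without MDA-2A (adjusted p = 5.5e-04; range 5.5e-04 to 0.979), interferon-stimulated genes without DU145 (0.010001; range 0.010001 to 0.964) and core histones without LNCaP (0.00901; range 0.00901 to 0.485), all higher. The ribosomal list had a median of 0.12, a mean of −0.02 and a test statistic below 0, and the DNA methylation list a median of 0.03, a mean of 0.01 and a test statistic below 0. Antigen presentation genes (2 tested), metallothioneins (1), endothelial markers (3) and S100 and squamous differentiation genes (4) were too few to test.

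The next comparison described each line by itself, without a test. In LNCaP 214 genes were at least 2-fold higher and 410 at least 2-fold lower, if the values are to base 2, which these counts assume. The counts were 412 and 339 in DU145, 349 and 404 in PC3, and 291 and 299 in MDA-2A. With ratios as deposited, genes at least 2-fold higher and lower numbered 157 and 544 in LNCaP, 318 and 407 in DU145, 236 and 576 in PC3, and 213 and 409 in MDA-2A, so the balance turned in DU145. Among the 4617 genes on all 4 arrays they were 139 and 75 in LNCaP, 182 and 67 in DU145, 203 and 191 in PC3, and 180 and 177 in MDA-2A, so most of the 2-fold lower genes of LNCaP and DU145 lacked a value on at least 1 other array. For spots listed on 1, 2, 3 and 4 arrays the deposited medians were −0.66, −0.42, −0.18 and 0.00 in LNCaP, and −0.25, −0.31, −0.27 and −0.12 in MDA-2A.

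In LNCaP the highest genes after PAGE2 and MAEL were ARLNC1, an androgen-regulated long non-coding RNA, at 4.53, GCNA at 4.37 and VAMP8 at 4.10. The lowest were GRIK1-AS1 at −5.93, COL8A1 at −5.91, LINC01939 at −5.75, POLR3B at −5.55 and LINC00446 at −5.31, each read from 1 spot and with no value on at least 2 of the other arrays. In DU145, TDRD9, a helicase of the germ-line piRNA pathway, was at 7.26, TMEM207 at 6.47 and GCNA at 6.02, beside PAGE2 and MAEL. DTX3 at −5.53, KCNMB1 at −4.42, RHBDD3 at −4.14, TAMALIN at −4.04 and SAMSN1 at −3.46 were its lowest. In PC3, CFAP251 was at 4.24, ADGRL4 at 3.97 and ZNF655 at 3.64, again beside PAGE2 and MAEL, and CALCOCO1 at −6.71, TRAF3 at −6.21, LINC01193 at −6.17, NECTIN1 at −4.67 and SYT12 at −4.26 were lowest. In MDA-2A the highest gene was TGM4, the prostate transglutaminase, at 8.07, where 3 spots gave 7.01 to 9.40. It was followed by PAGE2, DDIT4L at 5.91, HPSE2 at 5.89 and KRTAP10-11 at 5.61. BRIP1 at −7.47, ZNF385C at −5.87, GNAL at −5.64, HP1BP3 at −4.72 and DSEL at −4.53 were lowest there. The value of BRIP1 in MDA-2A came from 1 of its 4 spots.

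**Figure D2:**
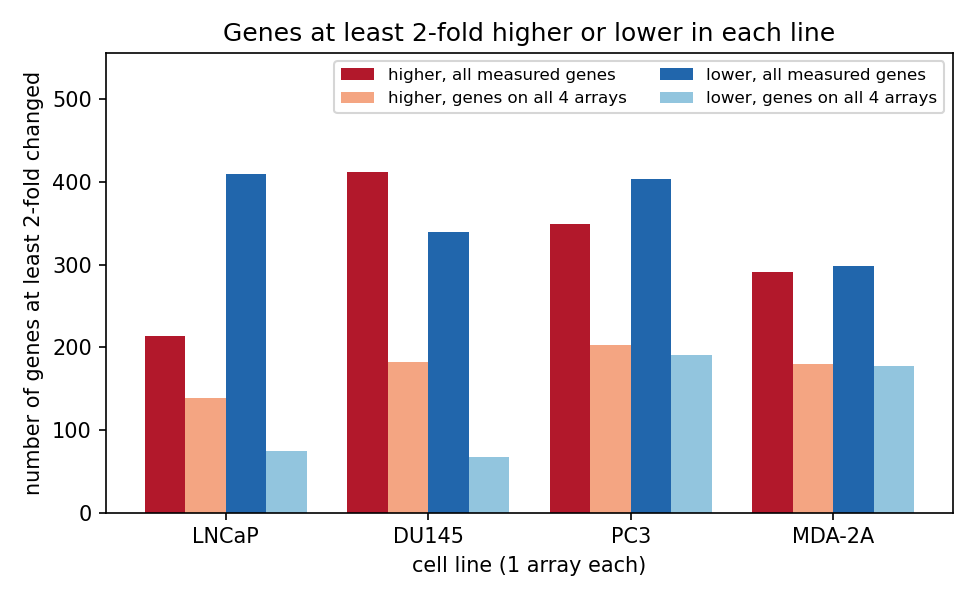
Number of genes (y axis) at least 2-fold higher or lower in each cell line (x axis, 1 array each). Dark bars count all measured genes and light bars the 4617 genes with a value on all 4 arrays; the 2-fold lower genes of LNCaP drop from 410 to 75 and those of DU145 from 339 to 67.

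Each list was also set, line by line, against random lists of as many genes. Cancer-testis genes had a median of 1.72 in DU145, where 18 of 29 measured members were at least 2-fold higher, among them RBM46 at 5.34, SSX3 at 3.95, TEX11 at 3.82, HORMAD1 at 3.56 and MAGEA6 at 3.39. Their medians were 0.57 in LNCaP, 0.41 in PC3 and 0.20 in MDA-2A, over 23, 18 and 18 measured members. The members thus differ between lines, and RBM46, for example, had a value in DU145 alone. Over the 25 members with a value in DU145 and in at least 1 other line, the median was 1.33 in DU145. For the mean of the other lines it was 0.26. Interferon-stimulated genes had a median of 1.44 in PC3, where all 23 measured members were above 0 and 17 were at least 2-fold higher. RTP4 was at 2.43, EPSTI1 at 2.36, HERC6 at 2.16, RSAD2 at 2.08 and the RNA sensors RIGI and IFIH1 at 2.004 and 1.86. The medians of the list were 0.26 in LNCaP, −0.02 in DU145 and 0.28 in MDA-2A. Leukocyte markers had a median of 0.98 over 6 members in PC3, with IL7R at 2.74 and ARHGDIB at 1.51, against 0.38 to 0.58 elsewhere. Cell cycle genes had a median of −0.70 in MDA-2A, where 1 of 28 measured members, GMNN at 0.12, was above 0 and 8 were at least 2-fold lower, such as CENPF at −1.998, MELK at −1.53 and PBK at −1.27. They had medians of 0.46 in LNCaP, 0.31 in DU145 and 0.61 in PC3. Among 10000 random lists these medians lay at percentile 100 for cancer-testis genes in DU145 and interferon-stimulated genes in PC3, and at 0 for cell cycle genes in MDA-2A. In LNCaP, cancer-testis genes, androgen-induced genes and genes of cholesterol and fatty acid synthesis also lay at 100, as did cell cycle genes in PC3 and the 5 measured S100 and squamous differentiation genes in MDA-2A. Genes reported as silenced in prostate cancer lay at 0.99 in LNCaP, with a median of −0.35 and 5 of 14 above 0, but at 97.3 in DU145 (0.31, 17 of 24), 88.6 in PC3 (0.25, 12 of 18) and 64.2 in MDA-2A (0.12, 9 of 12). Neuroendocrine and neuronal genes lay at 0.67 in LNCaP, or 7.03 among lists matched on the number of arrays, and at 94.0 in DU145. Members named here other than HERC6, IL7R, ARHGDIB and CENPF were chosen after their values were seen. The percentiles place a list within 1 array and not within repeated cultures.

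**Figure D3:**
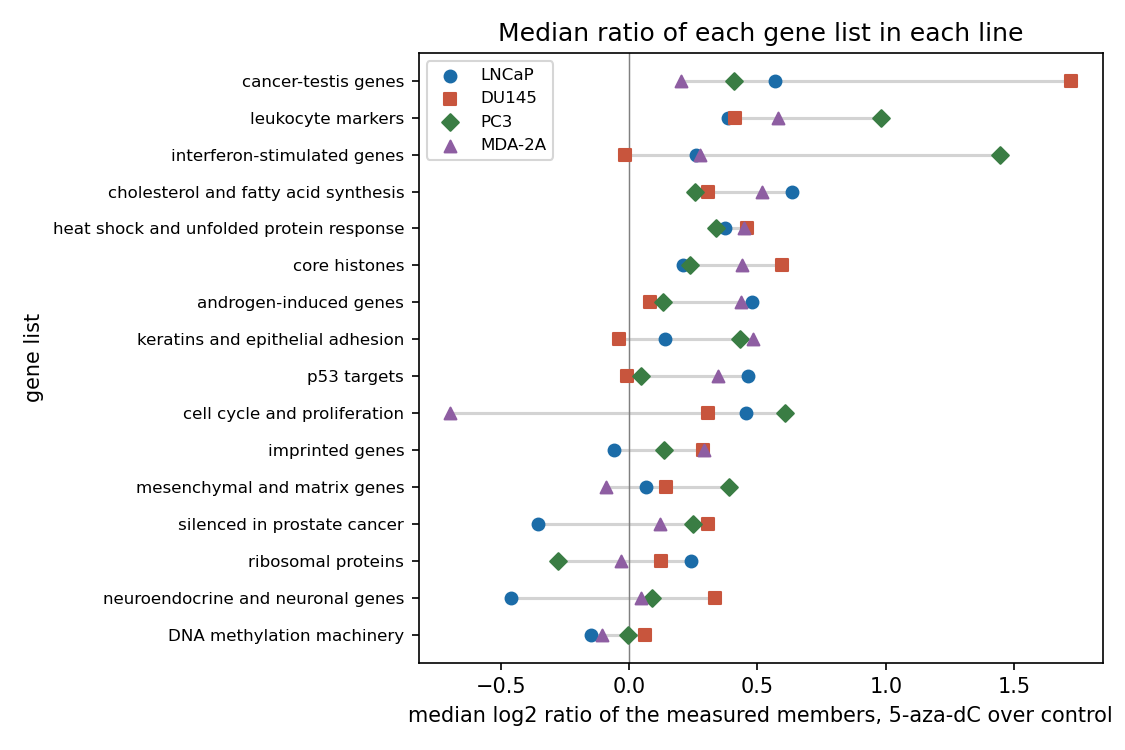
Median log2 ratio of the measured members (x axis, array median at 0) of the 16 gene lists with a median in every line (y axis). Symbols mark the 4 cell lines and grey bars their range; cancer-testis genes reach 1.72 in DU145, interferon-stimulated genes 1.44 in PC3 and cell cycle genes −0.70 in MDA-2A.

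The lines treated for 5 days, LNCaP and MDA-2A, were then compared with those treated for 3 or 4 days, DU145 and PC3. These pairs are also the androgen-sensitive and the androgen-insensitive lines, so time and line cannot be told apart. HPGD, the enzyme that inactivates prostaglandins, was the 1 gene of 4617 past the threshold, with a difference of 4.41 (limma adjusted p = 0.0318). Its ratios were 3.69 in LNCaP and 4.62 in MDA-2A against −0.10 in DU145 and −0.40 in PC3. The next differences did not pass: SIPA1L2 (2.81), AGR2 (2.13), REG4 (1.98) and LIMS1 (1.96) above 0, and GNAL (−2.98), DSEL (−2.68), HS6ST2 (−2.39), TBX15 (−2.16) and ZNF300 (−2.04) below, all with an adjusted p of 0.869. DSEL was read from different spots in MDA-2A (−4.53) and DU145 (−0.225). For GNAL the DU145 value averaged in a spot listed only there (−0.151), and the spot shared by all lines gave −1.434. At an unadjusted p under 0.05 there were 251 genes, 110 higher and 141 lower at 5 days, where chance gives 231, and the pairings of LNCaP with DU145 and of LNCaP with PC3 gave 241 and 124. HPGD lost its call with ratios as deposited (adjusted p = 0.0502), with centring within blocks of spots (0.0566), without DU145 (0.536) and without PC3 (0.506), its adjusted p ranging from 0.00435 to 0.536 over the alternatives. Its differences in these 4 fits were 4.40, 4.31, 4.56 and 4.26.

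By cameraPR 5 of 14 lists differed between these pairs. Androgen-induced genes were higher at 5 days (adjusted p = 0.0018; adjusted p = 0.523 with an estimated correlation), with a median of 0.36 against 0.10 over 22 members. HPGD, ELL2 at 2.83 in LNCaP and 0.81 in MDA-2A, and IGF1R at 0.64 and 1.13 were among them, the last 2 named after their values were seen. This list was not tested without HPGD, the 1 gene past the threshold, so how much of its call rests on HPGD is unknown. The median difference over the 22 members was 0.153. The p53 targets (0.49 against 0.04, adjusted p = 0.0224) and genes of cholesterol and fatty acid synthesis (0.54 against 0.23, adjusted p = 0.0247) were also higher at 5 days, and cell cycle genes (−0.14 against 0.52, adjusted p = 1.0e-04) and cancer-testis genes (0.30 against 1.03, adjusted p = 0.0314) lower. With an estimated correlation none passed, with adjusted p of 0.523 for the first 3, 0.751 for cell cycle genes and 0.616 for cancer-testis genes. Leaving out MDA-2A turned the direction of the cell cycle list (adjusted p = 0.858) and ended the calls of p53 targets (0.199), cholesterol genes (0.122) and cancer-testis genes (0.342). Calls also ended without LNCaP for p53 targets (0.0580) and cholesterol genes (0.1002), without DU145 for p53 targets (0.266) and cancer-testis genes (0.5001), and without PC3 for cholesterol genes (0.102). Over the alternatives adjusted p ranged from 1.2e-17 to 0.858 for cell cycle genes, 6.3e-05 to 0.523 for androgen-induced genes, 0.0142 to 0.523 for p53 targets, 0.0203 to 0.523 for cholesterol genes and 1.4e-04 to 0.616 for cancer-testis genes.

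The lines were compared as a whole by correlating their ratios across genes, which are not independent replicates. Pearson's r over 4617 genes lay between 0.284, for DU145 with MDA-2A, and 0.407, for DU145 with PC3, with a mean of 0.370. Spearman's rho lay between 0.263 and 0.381. Over genes read from several spots the mean r was 0.295. A set of 9 genes was at least 2-fold higher in all 4 lines and 4 were at least 2-fold lower, where shuffling the genes of each line gave at most 1. The 9 were PAGE2, MAEL, GCNA, INAVA, GPRC5A, ARRB1, BCAP31, NSDHL and SEC23B, and the 4 were FAM163B, IPO5, TCHP and TMEM44-AS1. BCAP31, SEC23B, TCHP and TMEM44-AS1 were named after their values were seen. All 4 arrays share the order of dyes, and a dye effect common to them, which was not measured, would add to both counts and to the correlations.

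Among the genes named in advance, CDKN1A, the cell cycle inhibitor p21, had a ratio of 2.48 in LNCaP, 0.56 in DU145 and 0.81 in MDA-2A, with a mean of 1.28 ± 1.04 (SD, n = 3; adjusted p = 0.146). KLK3, which encodes prostate-specific antigen, had ratios of 0.28, 0.33, 0.16 and 0.05 in LNCaP, DU145, PC3 and MDA-2A (adjusted p = 0.430). Caveolin 1 (CAV1) had −0.54 in LNCaP, 0.73 in DU145 and 1.16 in PC3 (adjusted p = 0.461). ALDH1A2, an enzyme of retinoic acid synthesis, was measured in DU145 at 2.90 and in PC3 at 1.51 and was not tested. GSTP1, DNMT1, CDKN2A, CDH1 and SFN had no value under these symbols here.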

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

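The tests of a dye effect, of brightness, of the sign patterns, of the state of the PC3 culture and of CDKN1A were chosen only after the results were seen. Those of position on the array and of testis RNA were written before their own results were seen. Centring within blocks, which the test of position uses, was itself added after the data had been seen.

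PAGE2 and MAEL rose past the threshold, and cancer-testis genes rose as a list across the lines and differed between the pairs of lines (adjusted p = 0.0314, lower at 5 days), though neither list call held with an estimated correlation (adjusted p = 0.485 and 0.616). DU145 minus the mean of the other lines had a median of 0.84 over 25 members, 22 of them above 0, and the highest of 10000 random lists reached 0.668, which argues against a dye effect that is the same on every array as the whole cause. For PAGE2 alone, with an SD of 0.0631 between the lines, a dye effect and induction cannot be told apart, because no array has the dyes swapped. RNA from testis stays open, since few of 41 abundant testis transcripts outside the list were measured and the lines could express some anyway. In DU145 11 of them had a median of 0.194 but values from −1.45 to 3.54, with an SD of 1.26, against 1.72 for the list. Those in LNCaP (8), PC3 (7) and MDA-2A (7) reached at most 0.434, 0.731 and 1.14, against list medians of 0.57, 0.41 and 0.20. The rule set in advance looked only at the medians in DU145, and by it the values argue against testis RNA. A condition on the spread of the members, which that rule did not hold, left the explanation open. Of the 8 sign patterns of the arrays, 1 gave as many genes past the threshold, the real one with 2, and the highest other gave 0; 8 patterns are too few for a share under 0.05.

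Interferon-stimulated genes stood at a median of 1.44 in PC3. After centring within blocks of spots the median was 1.58. The block medians of PC3 spanned 0.65, so shifts of whole blocks are too small to make up the 1.44. Centring could therefore hardly have removed it, and position within a block was not tested. Random lists matched on the number of arrays that list a gene reached at most 0.63, which argues against a bias of faint spots, as far as this number stands for brightness. A state of the PC3 culture or array apart from the drug stays open, since the series has 1 array of PC3. A response to the drug in PC3 is a hypothesis that the series cannot test further.

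Cell cycle genes stood at a median of −0.70 in MDA-2A and as a list differed between the pairs of lines (adjusted p = 1.0e-04, lower at 5 days). The list did not pass with an estimated correlation (adjusted p = 0.751) and turned without MDA-2A (0.858). Centring within blocks left the median at −0.69. The block medians of MDA-2A spanned 0.64, so this centring could not have raised the median to 0, and position within a block was not tested. The farthest matched random list lay at −0.356, which argues against a bias of faint spots. LNCaP, also treated for 5 days and with the highest CDKN1A ratio (2.48), had a cell cycle median of 0.457, with 23 of 31 members above 0. As 1 array it excludes neither a fall wherever CDKN1A is high nor an effect of the length of treatment, and these, the line and the state of the 1 culture of MDA-2A stay open.

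Other results stood out by the same rules. The 5-day lines differed from the other lines in HPGD (difference 4.41), androgen-induced genes (adjusted p = 0.0018), p53 targets (adjusted p = 0.0224) and genes of cholesterol and fatty acid synthesis (adjusted p = 0.0247), all higher at 5 days. With an estimated correlation the 3 lists had an adjusted p of 0.523 and did not pass. HPGD is itself a member of the androgen-induced list, which was not tested without it. In 6 of 70 genes 1 line lay far from the other 3, and in 0 of 16 lists. The 6 genes were VAMP8 in LNCaP (4.10), SYT12 in PC3 (−4.26), BRIP1 in MDA-2A (−7.47), CDK1 in MDA-2A (−0.16, others 0.85 to 0.92), MTF1 in PC3 (0.12, others 0.40 to 0.44) and IL7R in PC3 (2.74, others 0.41 to 0.72). Chance gives about 3.5 only for genes not chosen by their values. Genes such as VAMP8, SYT12 and BRIP1 were named for an extreme ratio in that line, so the 6 cannot be set against it. When all 19157 spots with a value on at least 3 arrays were tested, 7 spots without a gene name passed, 4 higher and 3 lower; the highest had a mean of 6.06 ± 0.48 (SD, n = 4).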

How the results depend on the processing

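Centring within blocks of spots or classes of spots, counts over genes on all 4 arrays, the list test on ranks and the list test without called genes were chosen only after the results were seen. Of the alternatives, 85 of the results that answer a comparison stayed on their side of the threshold or within 1.5 times the count, 38 were weaker, 15 stronger and 1 moved; of the single genes and lists 1203 stayed, 20 were weaker, 21 stronger and 2 reversed. Across the lines, 2 genes passed, both higher. The count was 1, PAGE2 without MAEL, with arrays scaled to the same spread, with genes on at least 2 arrays and with robust eBayes. The count was 0 with genes read from several spots (570 at an unadjusted p under 0.05). It was 4 with spots tested singly (2 lower) and 42 (30 higher, 12 lower) with genes on all 4 arrays, with or without array weights, where the genes adjusted over and the variance prior both changed. It was 1 to 3, all higher, leaving out each line, and 1326 (861 higher, 465 lower) at an unadjusted p under 0.05. Between the times, the count of 1 was 0 with ratios as deposited and with centring within blocks, 0 to 4 leaving out each line and 251 at an unadjusted p under 0.05. Where a line is left out, the lone line of its pair is assumed to vary like the others. At 3-fold, 56 genes were higher and 168 lower in LNCaP, 164 and 115 in DU145, 97 and 112 in PC3, and 103 and 89 in MDA-2A. Among genes on all 4 arrays the 2-fold counts were 139 and 75, 182 and 67, 203 and 191, and 180 and 177. Across the lines 3 lists passed, 0 with an estimated correlation and 5 on ranks. Between the times 5 passed, 0 with an estimated correlation and 1 to 6 leaving out each line. Without PC3 the interferon list reversed (adjusted p = 0.0421, higher at 5 days; 7.4e-13 to 0.243 leaving out each line), as did the cell cycle list without MDA-2A (adjusted p = 0.858; 1.2e-17 to 0.858). The mean correlation between lines was 0.295 over genes read from several spots. The cause of the other changes was not tested. Signal over background was not used here, so its limits are unknown.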

Other observations

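The tests of neighbouring genes and of long non-coding RNA genes were chosen before their results were seen, and the genes named in the next 2 paragraphs only after their values were seen, except TGM4, ABCG2, GREM1, NNAT, NEFL, NTS, AQP3 and ALOX15B, which the rule fixed in advance names.

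Some genes were past 2-fold on each of at least 3 spots. In MDA-2A these were TGM4 at 8.07, the transporter ABCG2 at 4.85 over 4 spots, the differentiation inhibitor ID2 at 1.40 and the desaturase SCD at 1.15, and lower CEP41 at −1.38. In LNCaP, CRISP3, a secreted protein of the prostate and other glands, was at 3.49, and TMEM38B at −2.06 and the cystine transporter SLC7A11 at −1.33 were lower. In DU145 the transcription factor DACH1 was at 3.07, the guanine deaminase GDA at 2.48 and PKIB at 2.13, with RBMS3 lower at −1.64 over 5 spots. In PC3 there were 8 higher, among them CLTRN at 2.99, the matrix protein CCN1 at 2.05, the interferon-responsive RNF213 at 1.94 and the BMP inhibitor GREM1 at 1.80, and 2 lower, LSAMP at −2.77 and CUX1 at −1.32.

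In DU145 single imprinted genes had high ratios, NNAT at 4.78, PEG10 at 3.03 and the non-coding MEG3 at 2.63. As a list they did not stand apart, with 4 of 12 at least 2-fold higher, TP73 at −0.94 and a median of 0.29 (percentile 90.4). Of the neuronal genes the neurofilament NEFL was at 2.74, neurotensin (NTS) at 2.36 and INA at 2.26, with 5 of 13 at least 2-fold higher, GRIA2 at −1.11 and a median of 0.33 (percentile 94.0). In MDA-2A, 3 of 5 measured genes of squamous differentiation were at least 2-fold higher, CLCA2 at 3.21, AQP3 at 2.56 and ALOX15B at 2.10. UHRF1, which guides DNA methylation to new strands, was at −4.09 in LNCaP. Its list, the DNA methylation machinery, had 8 of 17 members above 0 there and a median of −0.15 (percentile 9.56).

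A hypothesis was tested that neighbouring genes respond together, as they would if the drug opened whole regions. Over 4397 pairs of neighbouring measured genes, with a pair counted once in each line, both genes were at least 2-fold higher in the same line 32 times. The median of 10000 shuffles was 26 (permutation p = 0.139). Both were at least 2-fold lower 22 times, counted in the same way, against 16 (permutation p = 0.0901). Neither test decides the hypothesis.

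Long non-coding RNA genes had lower ratios than protein-coding genes. Spots not listed on every array also had lower deposited medians than spots listed on all 4 in each line, from −0.66 to −0.18 against 0.00 in LNCaP and from −0.31 to −0.25 against −0.12 in MDA-2A. Among genes on all 4 arrays the median of 132 long non-coding RNA genes lay −0.225 from that of protein-coding genes (−0.12 against 0.11), where the middle 95% of 10000 shuffles lay between −0.07 and 0.07. The difference thus remained among genes with a value on all 4 arrays. Listing on fewer arrays is not excluded as its cause, because the average of such a gene can include spots listed on fewer arrays. What else sets the classes apart was not tested. The medians of the 48 blocks of spots spanned 0.44 in LNCaP to 0.65 in PC3 and correlated between lines (r from 0.446 to 0.795).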
